A study of Saccharomyces cerevisiae with 16 samples.

How the data were processed

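The data were RNA sequencing libraries from WT, hrr25as and hrr25is yeast cells, 16 samples in 8 groups of 2. Per the labels' protocols, cells growing in YPD were at an OD600 of 0.3 and a temperature of 30°C when they were divided and treated for 1 hour. Total RNA was taken with hot phenol and depleted of ribosomal RNA, and 100 bp single-end reads were made on a HiSeq instrument. The protocol and the series design name DMSO and CMK as treatments, while the titles and characteristics of some samples name 3MBPP1; the groups follow the titles and characteristics. Doses and the strand setting of the read counting are not stated there. Nothing in the labels says that the replicates came from separate cultures, so p-values measure only the spread between these samples.

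Per the submitters' processing notes, reads were handled with CASAVA 1.8.2, STAR 2.3.0 and HTSeq 0.6.0 on build sacCer3. The column names are those of a DESeq comparison of 2 conditions, per the file headers, and its version is not given in the sources used here. The authors averaged the normalised counts of the libraries into a mean signal over each table and a mean for each of condition A and condition B, per the file headers. The deposited fold change is a ratio, the mean of condition B over the mean of condition A, and was checked against the means in every row. The deposited log2 values are the logarithm of that fold change, per the file headers. The p-values and adjusted p-values are those of the authors' own test, as deposited, and the adjusted ones equal a Benjamini-Hochberg adjustment over the table. The headers do not say which of A and B is DMSO.

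The plan, made before the data were examined, assumed read counts per sample with a quasi-likelihood test, and named the authors' deposited comparison as the fallback. The tables hold that comparison and no column of counts, so the authors' fold change, p and adjusted p were used as they stand, at an adjusted p under 0.05. In each of the 4 tables, every condition mean was the average of whole read counts divided by a pair of size factors. Solving for these gave 1 pair of whole counts for 99.98% to 100% of condition means, with 3 ambiguous means in the 3MBPP1 table of WT, and each listed feature had at least 1 read in every library. Recovery was tested on simulated data with the same size factors, where 100% of the means were recovered in each table. Recovered libraries carry no replicate number: within a condition they are told apart here only by their size factor, smaller or larger. The size factors of the CMK tables match a joint normalisation of 8 columns in which the library present in both tables has a column in each, and with it counted once they deviate by up to 7.62%.

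Depth was 4275991 to 34122412 counted reads per library. Shares of reads in single libraries have 95% Wilson intervals that reach at most 0.0306 percent of reads to either side for ribosomal protein genes and 0.0294 for small nucleolar RNA genes, which cover counting error only. Identifiers were matched to the R64 reference annotation for symbols and positions: 5978 of 6834 features in the 3MBPP1 table of WT, 5765 of 6258 in that of hrr25as and 5965 of 6760 in both CMK tables. Positions are on that assembly. Near-identical gene pairs, such as many ribosomal protein genes, HXT7 and its neighbour, and histone genes, share reads. A gene inside another, such as SNR24 in ASC1, may share reads with it, and how such reads were counted is not known here.

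Differences of effects between tables used a two-sided z test of the difference of deposited log2 fold changes, with standard errors implied by each fold change and its p, adjusted by Benjamini-Hochberg over the features in both tables; all such differences take condition A as the same treatment in each table. An implied error is too small where a deposited fold change lies near 0. On simulated data this test called 19.1%, 78.3% and 96.8% of planted log2 differences of 1, 2 and 4 in the 3MBPP1 pair of tables, with 9 false calls among 6246 features, and 6.56%, 43.7% and 76.5% in the CMK pair with 2 false calls. That simulation took the implied errors as true and drew the tables independently. It therefore tests neither errors that are too small near 0 nor the effect of a library present in both CMK tables. Overlaps used a two-sided Fisher exact test per direction, which treats features that move together as independent, so its p is too small for them. The 34 gene lists, fixed in the plan, cover ribosome production, transcription, stress, cell cycle, metabolism, transport and strain markers. They were tested with limma's cameraPR on the signed z of the deposited p at a preset correlation of 0.01, with adjustment over the lists. The test with an estimated correlation used limma's camera on the recovered reads instead, so its statistic differs as well. For CMK in hrr25is it includes the library present in both CMK tables. With 4 libraries per table it has little power, so a list that fails it is not thereby argued against. In a simulation of cameraPR the planted list was called in each table and 0 of the 33 other lists were. Its values were drawn independently for each gene. It therefore does not show how the test behaves where members of a list move together.

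The rule for named genes was: among features with a symbol, a mean normalised count of at least 20 and an adjusted p under 0.05, the 10 with the highest and the 10 with the lowest log2 fold change or difference, up to 2 called members at each end of a described list, and always HRR25, HIS3, LEU2 and URA3. Genes named outside it are said to be so, or are those of a count of 5 or fewer.

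Alternatives chosen after seeing the data were limma voom fits to the recovered reads with the recovered size factors or total reads, interactions in 1 fit, fits without the shared library, implied errors held at no less than the table's median, and the overlap of the 3MBPP1 tables. Fits without each library in turn were planned for counts and were run in limma on the recovered reads. Where a condition keeps 1 library, that library is assumed to vary like the others in the fit. Settings varied as planned were stricter and looser thresholds, a minimum fold of 2, a minimum mean count of 20, symbols on nuclear chromosomes, centred fold changes, and other list settings. On simulated data with 200 changed genes limma called 89.8% of 2-fold changes for 3MBPP1 in WT, 41.1% for 3MBPP1 in hrr25as, 21.5% for CMK in WT and 91.7% for CMK in hrr25is, with 12, 2, 4 and 7 false calls. All genes of a simulated table were given the same dispersion, which lets limma pool their spread more than real genes may allow. These percentages can therefore overstate what limma finds in the real tables. For CMK in hrr25is the simulated spread was that of condition A alone, with no shared library. The 91.7% therefore does not apply to the table as deposited. Software was R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.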

Results

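RNA was sequenced from cultures of the budding yeast Saccharomyces cerevisiae in which, per the labels, the chromosomal HRR25 gene was deleted and a copy was supplied on a plasmid. HRR25 encodes the casein kinase 1 delta/epsilon homologue of this yeast. The labels list 3 strains. WT cells carried unmodified HRR25 on a plasmid with the URA3 marker. The hrr25as cells carried the I82G form on a plasmid with the LEU2 marker, and the hrr25is cells a form with both I82G and I23C on the LEU2 plasmid. Per the labels, cells were treated for 1 hour with DMSO or with 1 of 2 inhibitors, 3MBPP1, an analogue of the kinase inhibitor PP1, or CMK, which the labels do not expand. The 16 samples formed 8 groups of 2, and each of the 4 deposited tables compared 2 of these groups: 3MBPP1 in WT, 3MBPP1 in hrr25as, CMK in WT and CMK in hrr25is. The headers of the authors' deposited tables call the groups condition A and condition B and do not say which is DMSO. Every fold change below is therefore condition B over condition A, and the inhibitor's own direction rests on that order. Reads counted on features ranged from 10505164 to 13998631 per library for 3MBPP1 in WT and from 4275991 to 6592340 for 3MBPP1 in hrr25as. They ranged from 9568820 to 34122412 for CMK in WT and from 16815301 to 34122412 for CMK in hrr25is.

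HRR25 and the plasmid markers were read in every library as a check on the strain labels, in reads per 1000000 counted reads of the library (RPM). HRR25 (YPL204W, chromosome XVI, 164276 to 165760) lay at 691 to 864 RPM in the CMK table of WT, against 117 to 166 in the 3MBPP1 table of WT and 123 to 166 in the 3MBPP1 table of hrr25as. RPM depends on what else fills a library. Small nucleolar and spliceosomal RNA genes took 31.4% to 38.2% of reads in the 3MBPP1 libraries of WT and 5.14% to 6.39% in those of hrr25as. A larger share lowers the RPM of all other genes, so like values or small differences between tables cannot be read as expression. URA3 (YEL021W, chromosome V, 116167 to 116970), which makes uracil and marks the WT plasmid, lay at 1541 to 1842 RPM in the CMK libraries of WT and at 91.0 to 120 in the 3MBPP1 libraries of WT. It was not listed for hrr25as. LEU2 (YCL018W, chromosome III, 91324 to 92418), which makes leucine and marks the other plasmid, lay at 71.5 to 99.4 RPM in hrr25as and at 0.132 to 1.67 in the CMK libraries of WT. In the 3MBPP1 libraries of WT, however, LEU2 lay at 38.6 to 54.4 RPM, and LYS2 and MET17, enzymes of lysine and methionine synthesis, lay at 45.6 to 51.2 and 271 to 459. LYS2 and MET17 stayed at or below 1.36 and 1.25 RPM in the CMK libraries of WT and were not listed for hrr25as. Both genes were singled out after their values were seen. The lowest LEU2 value rests on 2 reads, with a 95% Wilson interval of 0.0363 to 0.482 RPM. In the authors' deposited table of 3MBPP1 in WT, HIS3 (YOR202W) fell by 0.92 on the log2 scale (adjusted p = 0.00283), while HRR25 and LEU2 had log2 fold changes of 0.10 and -0.40 (adjusted p = 0.887 and 0.319). Deposited values for hrr25as were -0.04 for HRR25, -0.50 for LEU2 and -0.94 for HIS3, with adjusted p of 1, 0.782 and 0.212. For CMK in WT the authors' table gives log2 fold changes of 0.08 for HRR25, -0.28 for URA3, 2.10 for LEU2 and -0.01 for HIS3, each with an adjusted p of 1.

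**Figure D1:**
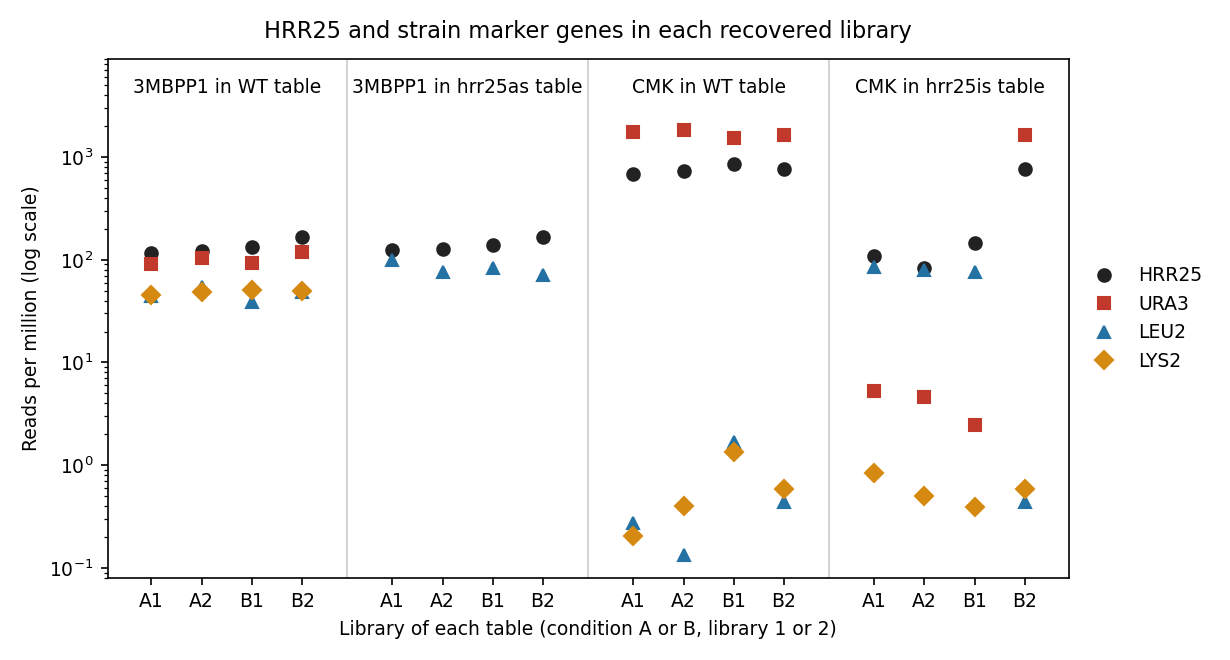
RPM (log axis) of HRR25, URA3, LEU2 and LYS2 in each recovered library of the 4 tables, grouped by condition A or B, 1 symbol per gene and library with no averaging. HRR25 is between 691 and 864 in the CMK libraries of WT, and library 2 of condition B in the hrr25is table has the URA3 value, 1629, of a WT library.

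Condition B of the hrr25is table contains a library that also stands in condition B of the CMK table of WT. Whole reads per library, recovered from the deposited condition means, were equal at each of the 6760 features in this library of 34122412 reads, while no other of the 120 pairs of libraries was equal at more than 1.79% of features. The tables therefore hold 15 distinct libraries. That library had 1629 RPM of URA3, 758 of HRR25 and 0.440 of LEU2, against 2.48 to 5.23, 84.1 to 144 and 75.4 to 85.8 in the other 3 libraries of the hrr25is table. Every deposited value of the hrr25is table averages this library with 1 other in condition B, so limma values without it are also given for this table below.

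WT cells of the 3MBPP1 set carry, per the labels, the unmodified kinase. Genes for ribosomal proteins, the building blocks of the ribosome, were lower in condition B: 130 of 137 fell in the authors' deposited table, with a median log2 fold change of -1.36 (adjusted over the list alone, 135 fell and 1 rose). Deposited log2 fold changes were -2.87 for RPL9A (YGL147C, chromosome VII, adjusted p = 4.41e-14), -2.07 for RPP2B (YDR382W, chromosome IV, adjusted p = 1.18e-27) and between -1.96 and -1.76 for RPS12, RPL14A, RPL21A, RPL29, RPS26B, RPL26B and RPS9B. Some genes of the drug response rose, 10 of the 23 on the list. In the authors' table the log2 fold change was 1.84 for GRE2 (YOL151W, chromosome XV, adjusted p = 1.85e-19), a methylglyoxal reductase. It was 1.71 for YOR1 and 1.42 for PDR5, both drug efflux transporters, and 1.64 for RSB1, which exports sphingoid bases. The remaining named genes that rose had deposited log2 fold changes between 1.40 and 1.71: GPG1, BDH2, ICT1, OSI1, CMI8 and GSP2. SNR71, a small nucleolar RNA, was also among the 10 with the lowest named values, at -1.83 in the deposited table.

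By group, 18 of the 34 lists passed the competitive test in this table. The ribosomal protein list had adjusted p = 3.49e-209, and adjusted p = 0.412 with an estimated correlation. Ribosome biogenesis genes, which assemble the ribosome, had a median log2 fold change of -0.52, and 46 of 119 fell in the deposited table, DBP2 at -1.11 and SNU13 at -1.09 among them (76 adjusted over the list alone). The list test gave adjusted p = 3.79e-28, and adjusted p = 0.412 with an estimated correlation. RNA polymerase I and III subunits had a median of -0.37 with 5 of 20 lower, RPA43 at -0.86 and RPA49 at -0.83 as deposited (7 adjusted over the list alone). Tested as a list, they had adjusted p = 5.81e-06, and adjusted p = 0.412 with an estimated correlation. The 40S maturation factors around Hrr25 had 2 of 14 lower, ENP1 at -0.66 and TSR2 at -0.65 in the deposited table, and a median of -0.45 (8 adjusted over the list alone). As a group they had adjusted p = 2.71e-04, but adjusted p = 0.468 with an estimated correlation. Small nucleolar and spliceosomal RNA genes had 10 of 78 lower, SNR71 and SNR38 (-1.33 as deposited) among them, and a median of -0.56 (10 adjusted over the list alone). At the preset correlation the test gave adjusted p = 8.54e-08, against adjusted p = 0.512 with an estimated correlation. Methionine and sulfur genes had 6 of 26 lower in the authors' table, SAM3 at -1.47 and MMP1 at -0.73, and a median of -0.43 (7 adjusted over the list alone). Against all other genes the result was adjusted p = 9.74e-06, and adjusted p = 0.412 with an estimated correlation. Amino acid biosynthesis genes under Gcn4 had 4 of 55 lower, LEU9 at -1.05 and HOM3 at -0.97 as deposited, and a median of -0.32 (4 adjusted over the list alone). The competitive test gave adjusted p = 1.18e-04, or adjusted p = 0.468 with an estimated correlation.

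Among the 11 lists that passed with higher values, the pleiotropic drug resistance genes under Pdr1 and Pdr3 had 10 of 23 higher in the authors' deposited table, including YGR035C at 2.20, and a median of 0.36 (10 adjusted over the list alone). For the whole list, adjusted p = 5.72e-12 was found, and adjusted p = 0.412 with an estimated correlation. General stress response genes had 8 of 50 higher, TFS1 at 1.36 and DCS2 at 1.06 as deposited, with a median of 0.64 (15 adjusted over the list alone). The list test gave adjusted p = 7.89e-12, and adjusted p = 0.468 with an estimated correlation. Proteasome subunit genes had a median of 0.42 and 3 of 33 higher, PRE3 at 0.60 and PUP2 at 0.54 in the deposited table (21 adjusted over the list alone). Tested as a list, they had adjusted p = 3.05e-11, and adjusted p = 0.412 with an estimated correlation. Respiration genes had 4 of 48 higher, CYC7 at 1.19 and LSC2 at 0.85 as deposited, and a median of 0.21 (4 adjusted over the list alone). As a group they had adjusted p = 2.19e-05, but adjusted p = 0.468 with an estimated correlation. Autophagy genes had 5 of 31 higher in the authors' table, ATG34 at 0.83 and ATG33 at 0.76, and a median of 0.18 (5 adjusted over the list alone). At the preset correlation the test gave adjusted p = 0.00342, against adjusted p = 0.412 with an estimated correlation. Histone genes had 2 of 10 higher, HTA1 and HHO1 both at 0.71 as deposited, and a median of 0.32 (2 adjusted over the list alone). Against all other genes the result was adjusted p = 0.00541, and adjusted p = 0.654 with an estimated correlation. The other 5 lists that passed had medians from 0.14 to 0.23 (DNA damage, G1/S, M/G1, Crz1 and ergosterol genes). Their adjusted p ranged from 0.00142 to 0.0333, and from adjusted p = 0.412 to 0.747 with an estimated correlation.

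In all, 504 of 6834 features passed an adjusted p of 0.05 in the authors' deposited table of 3MBPP1 in WT, 190 higher and 314 lower in condition B. A limma fit to the recovered reads called 577, 237 higher and 340 lower, and 471 features were called the same way by both. With total reads in place of size factors the median of all features shifted to 0.21, the ribosomal protein median to -1.11, and the fit called 365 features, 209 higher and 156 lower. Leaving out the smaller or the larger library of condition A left 75 or 203 calls in the limma fit.

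In hrr25as cells the same compound meets a kinase with a substitution that sensitizes it to such inhibitors. Condition B had less of HXT3 (YDR345C, chromosome IV, 1162957 to 1164660), a low-affinity glucose transporter, with a deposited log2 fold change of -3.20 (adjusted p = 1.91e-11), and less of ADE17, an enzyme of purine synthesis, at -2.52. ASC1, which encodes the RACK1 homologue on the small ribosomal subunit, fell by 2.47 in the authors' deposited table, PHO5, a secreted acid phosphatase, by 2.02, and GLN1, glutamine synthetase, by 1.99. The ribosomal protein genes RPS9B, RPS3, RPL9A, RPS13 and RPS9A had deposited log2 fold changes between -2.27 and -2.06. Condition B had more of RSB1 (YOR049C, chromosome XV), at 3.81 in the authors' table (adjusted p = 1.41e-14), and more of HSP12, a stress protein of the plasma membrane, at 2.99. The other named genes that rose in the deposited table were BDH2 at 2.98, SNR56 at 2.93, GAC1, a glycogen-related regulator of the phosphatase Glc7, at 2.73, ZNF1 at 2.70, REC104, a gene of meiotic recombination, at 2.68, SNR71 at 2.65, HXT7, a high-affinity glucose transporter, at 2.52, and GRE1 at 2.49.

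Of the 34 lists, 19 passed in hrr25as. Ribosomal protein genes fell in 117 of 137 cases in the authors' deposited table, with a median of -1.41 (129 adjusted over the list alone). The competitive test gave adjusted p = 5.03e-131, or adjusted p = 0.33 with an estimated correlation. Ribosome biogenesis genes had a median of -0.52, with 2 of 119 lower, SNU13 at -1.12 and HAS1 at -1.01 as deposited (1 adjusted over the list alone). For the whole list, adjusted p = 1.28e-15 was found, and adjusted p = 0.358 with an estimated correlation. The 40S maturation factors and the RNA polymerase I and III subunits had medians of -0.50 and -0.57, with 0 members past the threshold of the authors' test over all genes or over the list alone. The list tests gave adjusted p = 8.18e-04 and 9.69e-05, and adjusted p = 0.33 with an estimated correlation for both. General stress genes had 17 of 50 higher, HSP12 and GRE1 among them, and a median of 0.87 (27 adjusted over the list alone). Tested as a list, they had adjusted p = 1.45e-25, and adjusted p = 0.251 with an estimated correlation. Pleiotropic drug resistance genes had 4 of 23 higher, RSB1 and YGR035C (2.84 as deposited) among them, and a median of 0.78 (5 adjusted over the list alone). As a group they had adjusted p = 2.59e-09, but adjusted p = 0.358 with an estimated correlation. Gcn4 genes had 10 lower and 1 higher of 54 in the deposited table, HIS4 at -1.60, ILV3 at -1.49 and SER3 at 1.10, and a median of -0.68 (15 and 1 adjusted over the list alone). At the preset correlation the test gave adjusted p = 1.57e-09, against adjusted p = 0.442 with an estimated correlation. Genes of the G2/M cluster had 3 of 23 lower, CLB1, a mitotic cyclin, at -1.31 and HOF1, a cytokinesis factor, at -1.24 as deposited, and a median of -0.62 (10 adjusted over the list alone). Against all other genes the result was adjusted p = 7.02e-08, and adjusted p = 0.33 with an estimated correlation. Phosphate starvation genes had 4 of 19 lower, PHO5 and PHO11 (-1.88 as deposited) among them, and a median of -0.59 (6 adjusted over the list alone). The competitive test gave adjusted p = 1.9e-06, or adjusted p = 0.33 with an estimated correlation. Heat shock chaperone genes had 5 of 26 lower in the authors' table, HSP60 at -1.57 and SSC1 at -1.56, both mitochondrial chaperones. The list median was -0.21 and turned to 0.10 under total reads, or -0.24 relative to all features (5 adjusted over the list alone). For the whole list, adjusted p = 0.0014 was found, and adjusted p = 0.64 with an estimated correlation. Small nucleolar RNA genes had 8 of 78 higher, SNR56 and SNR71 among them, and a median of 0.25 (9 adjusted over the list alone). The list test gave adjusted p = 0.00186, and adjusted p = 0.454 with an estimated correlation. Glucose-repressed genes had 2 of 32 higher in the deposited table, HXT7 and ADR1 (1.21), and a median of 0.40 (2 adjusted over the list alone). Tested as a list, they had adjusted p = 0.00314, and adjusted p = 0.33 with an estimated correlation.

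Altogether 270 of 6258 features passed in the authors' deposited table of 3MBPP1 in hrr25as, 75 higher and 195 lower in condition B. The limma fit called 189, 56 higher and 133 lower, with 183 called the same way by both. GLN1 was outside its threshold (adjusted p = 0.052). Under total reads the median of all features shifted to 0.34, the ribosomal protein median was -1.08, and 54 features were called, 41 higher and 13 lower. Without the smaller or the larger library of condition B the limma fit called 475 or 513.

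**Figure D2:**
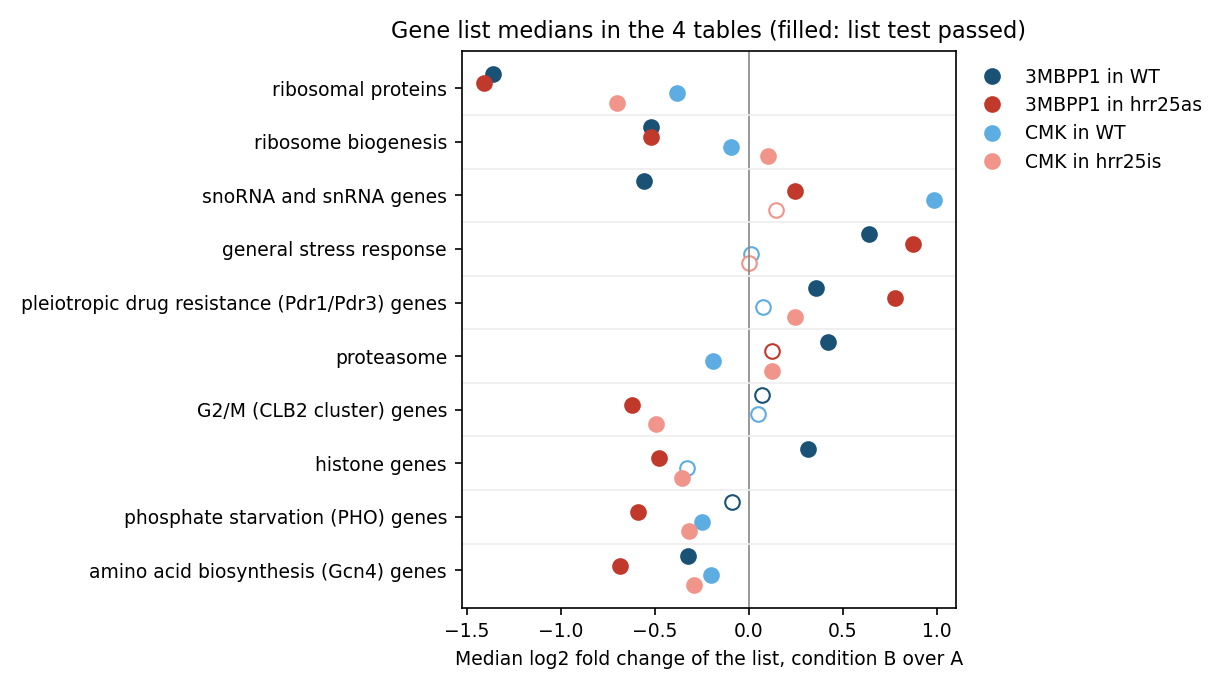
Median deposited log2 fold change, condition B over A, of 10 of the 34 gene lists in each of the 4 tables; filled points passed the list test at the preset correlation and open points did not. The ribosomal protein median is below 0 in each table, at -1.36, -1.41, -0.38 and -0.70, while the small nucleolar RNA median is -0.56 in WT with 3MBPP1 and 0.98 in WT with CMK.

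Set side by side, the 3MBPP1 tables of WT and hrr25as had 113 ribosomal protein genes lower in both and differed at HXT3, ADE17 and small nucleolar RNA genes, among others. The plan meant this comparison to separate effects that depend on the sensitized kinase from effects also seen with the unmodified one. It takes condition A as the same treatment in both tables and the strains as alike apart from the kinase, while their LYS2 and MET17 values differ as given above. Of 6246 features in both deposited tables, 141 fell in both where 9.80 would be shared by chance (two-sided Fisher exact p = 2.29e-151). In the same way 20 rose in both where 2.28 would be (Fisher exact p = 3.16e-14). The Fisher test counts each feature as independent, while 113 of the 141 were ribosomal protein genes, which moved together. This overlap was added after the data were seen. SNR13 and SNR71 passed in opposite directions: the authors' tables give -1.28 and -1.83 in WT, 1.71 and 2.65 in hrr25as. HXT3 had a deposited log2 fold change of 0.23 in WT and -3.20 in hrr25as, a difference of -3.43 (adjusted p = 2.46e-10), and ADE17 had 0.27 and -2.52, a difference of -2.79 (adjusted p = 5.22e-10). RIB4, a riboflavin synthesis gene, differed by -1.57, GCV1, of glycine cleavage, by -1.54, HTA1, a histone H2A gene, by -1.44, and HSP60, URA1, ARI1, YHI9 and ACO1 by -1.43 to -1.30, all from the deposited values. YHI9 in hrr25as and ACO1 in WT have a deposited value near 0, at 0.02 and 0.03, and so too small an implied error. The greater changes in hrr25as were SNR71 at 4.48, SNR56 at 4.16, SNR13 at 2.99, REC104 at 2.93, ZNF1 at 2.88, SNR66 at 2.54, SNR47 at 2.29, RSB1 at 2.17 and SER3 at 1.43.

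The z test of the difference passed for 25 of the 6246 features, 15 greater and 10 smaller in hrr25as, or 14 greater and 2 smaller with each implied error at least the median of its table. The interaction in a limma fit passed for 5: HXT3, ADE17, RIB4, SNR13 and SNR71. The full fit had 684 features at an unadjusted p under 0.05. The limma interaction passed for 0 features without any 1 of the 4 WT libraries or without the smaller library of condition A of hrr25as, and 15 without the larger library of condition B of hrr25as. Among lists, 13 passed for the difference. Small nucleolar RNA genes, which with spliceosomal RNAs took 31.4% to 38.2% of reads in the WT libraries and 5.14% to 6.39% in those of hrr25as, had a median difference of 0.88 with 5 of 78 greater (10 adjusted over the list alone). As a group they had adjusted p = 6.18e-20, but adjusted p = 0.53 with an estimated correlation. G2/M cluster genes had a median difference of -0.69 with 0 of 23 called by the z test over all genes or over the list alone. At the preset correlation the test gave adjusted p = 4.59e-11, against adjusted p = 0.121 with an estimated correlation. Histone genes had a median difference of -0.65 with HTA1 called (2 adjusted over the list alone). Against all other genes the result was adjusted p = 6.07e-07, and adjusted p = 0.53 with an estimated correlation. Phosphate starvation genes had -0.54 with 0 of 19 called (1 adjusted over the list alone). The competitive test gave adjusted p = 1.11e-06, or adjusted p = 0.306 with an estimated correlation. The ribosomal protein median difference was -0.05, and that list did not pass (adjusted p = 0.399). Across the 6246 features, which are not independent replicates, the deposited fold changes had a Pearson r of 0.39.

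**Figure D3:**
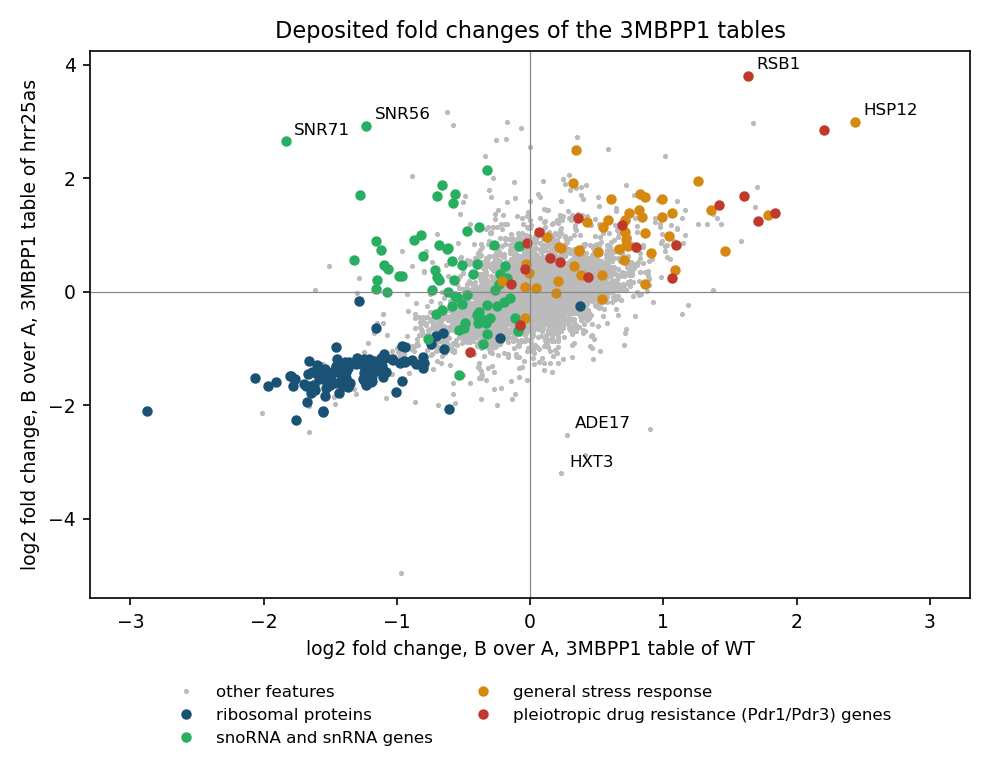
Deposited log2 fold change, condition B over A, of 3MBPP1 in WT (horizontal) and in hrr25as (vertical) for 5509 features with a mean normalised count of at least 20 in both tables, 1 point per feature, coloured by gene list. Of these, 3504 have the same sign in both, and HXT3, ADE17 and SNR71 lie far from the diagonal.

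CMK was also given to WT cells, which carry no added cysteine in the kinase. Every feature that passed in the authors' deposited table was a small nucleolar RNA gene higher in condition B; these RNAs guide chemical modification of ribosomal RNA. SNR61 (chromosome XII, 794486 to 794575) had a deposited log2 fold change of 3.70 (adjusted p = 9.69e-05), SNR79 of 2.28 (adjusted p = 1.7e-06), SNR50 of 2.17, SNR66 of 2.15 and SNR67 of 2.13. SNR45, SNR74, SNR47 and SNR24 had deposited values of 1.85, 1.81, 1.64 and 1.41. SNR24 lies inside ASC1 on chromosome XIII, at 499984 to 500072. Small nucleolar and spliceosomal RNAs took 9.14% and 11.1% of reads in the libraries of condition A, a share between these in the smaller library of condition B and 14.1% in the larger. tRNA genes took 0.799% in the smaller library of condition B against 0.067% to 0.10% in the other 3.

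In numbers, 9 of 6760 features passed, 9 higher and 0 lower, with 68 at an unadjusted p under 0.05 by the authors' test. Limma on the recovered reads called 0, with 93 at an unadjusted p under 0.05. Leaving out 1 library moved the limma count to 19 or 3 without the smaller or larger library of condition A and to 61 without the smaller of condition B. Without the larger of condition B, the library shared with the hrr25is table, it was 945. Of the lists, 12 passed, 2 higher and 10 lower. The small nucleolar RNA list had a median of 0.98, with 9 of 80 higher in the deposited table (21 adjusted over the list alone). For the whole list, adjusted p = 1.08e-74 was found, and adjusted p = 0.844 with an estimated correlation. The meiosis and sporulation list had a higher median, 1.16, and the glucose-repressed list had 0.69, with no member called in either. LEU2 and LYS2, with 20 reads or fewer per library, also had more RPM in each library of condition B than of A. MET17, with 12 reads or fewer, did so only in the smaller library of condition B. Whether low counts account for these 2 medians was not tested. Ribosomal protein genes had a median of -0.38 with 0 members called by the authors' test over all genes or over the list alone. The list test gave adjusted p = 9.12e-19, and adjusted p = 0.844 with an estimated correlation. Proteasome genes had a median of -0.19 and Gcn4 genes of -0.20, again with 0 members called. Tested as lists, they had adjusted p = 6.67e-04 and 0.00478, and adjusted p = 0.844 with an estimated correlation for both. Total reads shifted the median of all features to 0.14 and turned the ribosome biogenesis median from -0.10 to 0.02, which relative to all features is -0.12.

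CMK in hrr25is cells tests the inhibitor on the kinase form with I82G and I23C, in a table that holds the shared library. PHO5 (YBR093C, chromosome II, 429548 to 430951) fell by 2.46 on the log2 scale in the authors' deposited table (adjusted p = 5.5e-10), and the pheromone gene MF(ALPHA)2 fell by 1.53 (adjusted p = 4.25e-04). URA3, the WT plasmid marker, had a deposited log2 fold change of 7.16 (adjusted p = 9.56e-06), and HRR25 had 1.98 (adjusted p = 1), values that include the shared library. LEU2 and HIS3 had deposited values of -1.52 and -0.73, each with an adjusted p of 1. Without the shared library, in a limma fit to the 3 own libraries of the table, URA3 turned to -1.38 (adjusted p = 0.00299) and HRR25 to 0.19 (adjusted p = 0.645). LEU2, HIS3 and MF(ALPHA)2 had -0.53, -0.92 and -1.70 there (adjusted p = 0.0733, 0.00117 and 4.69e-11). With the spread pooled over the 7 distinct CMK libraries none of these 5 genes passed (adjusted p = 0.2 for MF(ALPHA)2, the lowest). In the fit to the 3 own libraries ADE17 had a log2 fold change of -3.05, PHO5 of -2.81 and MET6, the methionine synthase, of -2.66. HXT1, a low-affinity glucose transporter, had -2.28, and RPS13, HIS4, SHM2, CYC1, ASC1 and SAM2 had -2.17 to -1.94. In that fit REC104 had 3.54, SNR53 3.14, CTR2, a vacuolar copper transporter, 2.67, SNR10 2.25, SNR71 2.05, SNR56 2.03, and AIM26, PRR2, SNR48 and GRE1 1.79 to 1.68. Condition B is then a single library, whose spread is taken from condition A.

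Over all genes, 3 of 6760 features passed in the authors' table (1 higher, 2 lower; 154 at an unadjusted p under 0.05), and limma with all 4 libraries called 0 (363 at an unadjusted p under 0.05). Without the shared library limma called 897 (380 higher, 517 lower) with the spread of the 3 own libraries, and 1, PHO5 (adjusted p = 0.0498), with the spread pooled over the 7 distinct CMK libraries. Leaving out the other library of condition B gave 164, and leaving out the smaller or larger of condition A gave 8 or 2. Of the lists, 18 passed. Ribosomal protein genes had a median of -0.70, with 0 called by the authors' test over all genes (32 lower adjusted over the list alone). As a group they had adjusted p = 7.36e-103, but adjusted p = 0.595 with an estimated correlation. Without the shared library their median was -1.05. G2/M cluster genes had a median of -0.49 with 0 of 23 called either way, and -0.50 without the shared library. At the preset correlation the test gave adjusted p = 2.62e-14, against adjusted p = 0.595 with an estimated correlation. Phosphate starvation genes had a median of -0.32, with PHO5 the 1 called of 19 (1 adjusted over the list alone), and -0.57 without the shared library. Against all other genes the result was adjusted p = 1.39e-13, and adjusted p = 0.595 with an estimated correlation. Gcn4 genes had a median of -0.29 with 0 called either way. The competitive test gave adjusted p = 4.37e-07, or adjusted p = 0.794 with an estimated correlation. Total reads turned this median to 0.01, or -0.32 relative to all features, and the own libraries gave it as -0.53. The medians of the iron regulon, 0.28, the casein kinase 1 family, 0.10, and the marker genes, 0.62, turned to -0.17, -0.01 and -0.72 without the shared library. Total reads shifted the median of all features to 0.33 and that of the ribosomal protein genes to -0.39.

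Between hrr25is and WT, the CMK effects differed at small nucleolar RNA genes, PHO5 and a pair of ribosomal protein genes. The difference of deposited log2 fold changes was -2.59 for SNR79 (adjusted p = 0.00149), -2.45 for SNR50, -2.29 for SNR66, -2.26 for SNR67 and -1.99 for SNR45. PHO5 differed by -2.18 (adjusted p = 0.014), RPL41B by -1.98, RPL39 by -1.55 and MF(ALPHA)2, with a deposited WT value of -0.03 and so too small an implied error, by -1.49, all computed from the authors' tables. In total 9 of 6760 features passed the z test, 0 greater and 9 smaller in hrr25is (69 at an unadjusted p under 0.05). The limma interaction with the shared library used once passed for 0 (354 at an unadjusted p under 0.05) and for 27 without the smaller library of condition B of WT. The z test treats the tables as independent, which the shared library breaks. Small nucleolar RNA genes had a median difference of -0.75 with 5 of 80 smaller (8 adjusted over the list alone). For the whole list, adjusted p = 1.15e-39 was found, and adjusted p = 0.834 with an estimated correlation. Ribosomal protein genes had -0.34 with 2 of 137 smaller (2 adjusted over the list alone). The list test gave adjusted p = 1.07e-14, and adjusted p = 0.721 with an estimated correlation. G2/M genes had -0.50 and proteasome genes 0.31 with 0 called by the z test. Tested as lists, they had adjusted p = 3e-07 and 9.49e-06, and adjusted p = 0.627 and 0.721 with an estimated correlation. With the shared library used once, in WT, the median limma differences of these 4 lists were -0.71, -0.59, -0.51 and 0.60, in the order given.

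The compounds were also compared with each other, although the labels give no doses. In WT cells the difference of CMK minus 3MBPP1 passed for 19 ribosomal protein and 7 small nucleolar RNA genes, all greater with CMK, and for 2 drug resistance genes, both smaller. SNR74 differed by 2.97 (adjusted p = 2.06e-05), SNR79 by 2.90, SNR66 by 2.81, SNR57 by 2.78, RPL9A by 2.76 (adjusted p = 1.43e-04), RPL41A and SNR50 by 2.74, and RPL41B, SNR47 and RPL29 by 2.20 to 2.16, from the authors' deposited values. YOR1 differed by -1.65 (adjusted p = 3.17e-07) and GOR1, a glyoxylate reductase, by -1.36. The z test passed for 44 of the 6709 features in both tables, 37 greater and 7 smaller. Of these, 11 had 1 of the deposited log2 fold changes under 0.05 in size, where the implied error is too small. RFA2, GAD1, BXI1, REA1, RPL7B, PWP1 and HIS3 are such genes, with differences of -0.86, -0.82, -0.80, 0.65, 0.70, 0.73 and 0.91. FCY2, a purine and cytosine permease, differed by 0.92. With each implied error at least the median of its table, 6 passed. The limma interaction passed for 0 (596 at an unadjusted p under 0.05), but for 1292 without the larger and 50 without the smaller library of condition B of the CMK table. The ribosomal protein list had a median difference of 1.00, with 19 of 137 greater (45 adjusted over the list alone). As a group they had adjusted p = 1.69e-59, but adjusted p = 0.578 with an estimated correlation. The small nucleolar RNA list had 1.55 with 7 of 78 greater (29 adjusted over the list alone). At the preset correlation the test gave adjusted p = 8.58e-41, against adjusted p = 0.557 with an estimated correlation. The drug resistance list had -0.30 with 2 of 23 smaller, YOR1 and YGR035C (6 adjusted over the list alone). Against all other genes the result was adjusted p = 1.56e-07, and adjusted p = 0.557 with an estimated correlation. No feature passed in the same direction with both compounds in WT (0 by the authors' test at an adjusted p of 0.05, where 0.255 would be shared by chance among higher features), and SNR74 passed in opposite directions, at -1.16 with 3MBPP1 and 1.81 with CMK.

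In the sensitized strains, where strain and compound change together, CMK in hrr25is minus 3MBPP1 in hrr25as passed for 4 features, 2 of them general stress genes with smaller values. GPH1, glycogen phosphorylase, differed by -2.21 and SNR66 by -2.03 in the authors' deposited values, each with an adjusted p of 0.042. Without the shared library their limma differences were -1.74 and -1.91 and did not pass (adjusted p = 0.243 and 0.455). GAD1 differed by -1.45 and ILV3 by 1.51, both with a deposited hrr25is value near 0 and so too small an implied error. Without the shared library the limma difference of ILV3 was -0.20. These 4 of 6253 features passed the z test, 1 greater and 3 smaller (139 at an unadjusted p under 0.05), while the limma interaction without the shared library passed for 0 (407 at an unadjusted p under 0.05), for 5 without the smaller and for 4 without the larger library of condition B of hrr25as. General stress genes had a median difference of -0.91 with 2 of 50 smaller (15 adjusted over the list alone). The competitive test gave adjusted p = 1.02e-36, or adjusted p = 0.0406 with an estimated correlation. Without the shared library the median limma difference of this list was -0.81. Ribosome biogenesis genes had 0.65 and ribosomal protein genes 0.70, with 0 called by the z test over all genes or over the list alone. For these 2 lists adjusted p = 1.7e-38 and 2.38e-43 were found, and adjusted p = 0.183 and 0.57 with an estimated correlation. Their median limma differences without the shared library were 0.75 and 0.38. Of the features lower in the deposited tables, 1, PHO5, fell in both sensitized strains, where 0.0624 would by chance (two-sided Fisher exact p = 0.0614), and 0 rose in both. PHO5 also fell in the deposited table of 3MBPP1 in WT, by 0.61 (adjusted p = 0.0277). With limma calls and the shared library left out, 108 fell in both, where 10.7 would by chance (Fisher exact p = 5.56e-98), and 22 rose in both, where 3.06 would (Fisher exact p = 3.45e-14). By limma calls, 100 features also fell in both 3MBPP1 tables, of WT and hrr25as, and 15 rose in both. The overlap is therefore not shown to be particular to the sensitized strains. How many of the 108 were ribosomal protein genes, or also fell in WT, was not counted. The hrr25is calls in the overlap of the sensitized strains set a single library of condition B against the spread of condition A. With the spread pooled over the 7 distinct CMK libraries, only PHO5 fell in both, where 0.0213 would by chance (Fisher exact p = 0.0213), and 0 rose in both.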

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

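The tests of the pattern in the ribosomal protein genes against lists matched on mean count and on gene length were chosen before their result was seen; its tests of scaling and of strain, the tests of explanations for the library and marker patterns, and the limma interactions were chosen after. The differences between effects were planned.

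The 3MBPP1 effects in hrr25as and in WT differed at 25 features and 13 gene lists, by the z test of the difference and by the list test on it, with 0 of the lists kept with an estimated correlation. HXT3 differed by -3.43 on the log2 scale, ADE17 by -2.79, RIB4 by -1.57, SNR13 by 2.99 and SNR71 by 4.48, and these 5 also passed the interaction in a limma fit. That interaction passed for no feature without any 1 of the 4 WT libraries, 0 in each case by limma, with 684 features at an unadjusted p under 0.05 in the full fit. The CMK effects in hrr25is and in WT differed at 9 features and 11 lists in tables that share a library, with 0 features by the limma interaction (354 at an unadjusted p under 0.05) and 0 lists with an estimated correlation. The CMK and 3MBPP1 effects in WT differed at 44 features and 17 lists, 11 of the features with too small an implied error, with 0 features by limma (596 at an unadjusted p under 0.05) and 0 lists with an estimated correlation. The CMK effect in hrr25is and the 3MBPP1 effect in hrr25as differed at 4 features and 17 lists, with 0 features by limma without the shared library (407 at an unadjusted p under 0.05) and 1 list with an estimated correlation.

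A library in condition B of the hrr25is table has the markers of a WT library: 1629 reads of URA3 and 0.440 of LEU2 per 1000000 (RPM). Carry-over of WT reads into an hrr25is library is argued against by LEU2, which stands at 0.583% of the lowest other hrr25is library. Read counts equal to those of a WT library in the CMK table at 100% of features are consistent with the same library having been entered in both tables. The labels alone do not tell whether its cells were WT or hrr25is. In the CMK libraries of WT, URA3, LEU2 and HRR25 spanned 1541 to 1842, 0.132 to 1.67 and 691 to 864 RPM. In the other hrr25is libraries they spanned 2.48 to 5.23, 75.4 to 85.8 and 84.1 to 144. At 1629, 0.440 and 758 RPM, the values of the shared library argue against hrr25is cells. No biological explanation was tested.

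WT libraries of the 3MBPP1 set hold LEU2, LYS2 and MET17 reads, which the WT libraries of the CMK set nearly lack. Carry-over from hrr25as libraries is argued against, since LYS2 is at 45.6 RPM or more in each of the 4 WT libraries and is not listed for hrr25as. A WT strain with other markers than in the CMK set remains open: the lowest LYS2 value is 33.6 times the highest in the CMK set, which restates the pattern and does not test it. If it were so, strain background would differ along with the kinase allele between the 3MBPP1 tables, and the differences above would include it. The labels give the same strain for both WT sets, which the marker values argue against. URA3 and HRR25 also differed, at 91.0 to 120 and 117 to 166 RPM in the 3MBPP1 set. In the CMK set of WT they lay at 1541 to 1842 and 691 to 864. Small nucleolar and spliceosomal RNA genes took a larger share of reads in the 3MBPP1 set of WT, which lowers the RPM of other genes there. Which cells the 3MBPP1 set held cannot be told from these values.

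Ribosomal protein genes were lower in condition B of both 3MBPP1 tables, with medians of -1.36 in WT and -1.41 in hrr25as. Lower values of all highly expressed or all short genes are argued against: among 10000 random lists the lowest median was -0.37 when matched on mean count and -0.17 when matched on gene length. Scaling is argued against by their share of reads, at most 6.16% in a B library and at least 10.3% in an A library. A response that needs the sensitized kinase is argued against by the WT table, where 94.9% of these genes fell, as long as its cells carry the unmodified kinase as labelled. The median difference between the strains was -0.05 (list test, adjusted p = 0.399). A response to the compound or to the treatment of the cultures that both strains share remains open. The list did not pass with an estimated correlation, a test that has little power with 4 libraries per table and so cannot decide.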

How the results depend on the processing

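Thresholds, minimum counts and folds, centring and list settings were planned; limma fits to the recovered reads, scaling by total reads, fits without the shared library, held-up implied errors and the 3MBPP1 overlap were chosen after the data were seen. Of the alternative values of counts of genes and lists, 126 stayed within 1.5 times the reported count and 66 did not. Some of the 126 could not differ. For single tables, adjusting every deposited p again repeats the authors' adjustment, and centring leaves each p unchanged. Stricter settings could not change an overlap that was already empty, such as that of features higher in both sensitized strains. Limma interactions that were empty with and without a library are also among the 126. The 126 therefore overstates how stable the counts are. With total reads, which shift all features alike, the balance of the limma calls moved from 237 higher and 340 lower to 209 and 156 for 3MBPP1 in WT, and from 56 and 133 to 41 and 13 for 3MBPP1 in hrr25as. Called lists changed direction, and were then not called, in 4 cases with an estimated correlation and 5 with limma statistics, all in comparisons that use the hrr25is table. Where a value below differs and its construction gives no reason, the cause was not tested.

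A minimum fold of 2 left 203 genes for 3MBPP1 in WT. In limma fits, total reads gave 365 for 3MBPP1 in WT and 54 for 3MBPP1 in hrr25as. Limma on all 4 libraries gave 0 for CMK in WT and 0 for CMK in hrr25is (93 and 363 at an unadjusted p under 0.05), and for hrr25is without the shared library 897, or 1 with the spread pooled over 7 libraries. Leaving out 1 library in turn gave limma counts of 75 to 721, 169 to 513, 3 to 945 and 2 to 897 in the tables of 3MBPP1 in WT, 3MBPP1 in hrr25as, CMK in WT and CMK in hrr25is.

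The difference of 3MBPP1 effects, 25 features, became 16 at an adjusted p under 0.01, 16 with implied errors at least the table's median and 5 by the limma interaction, 0 to 15 without 1 library. The difference of CMK effects, 9, became 0 with such errors (z test, 34 at an unadjusted p under 0.05) and 0 by limma (354 unadjusted), 0 to 27 without 1 library. The compound difference in WT, 44, became 25 at an adjusted p under 0.01, 6 with such errors and 0 by limma (596 unadjusted), 0 to 1292 without 1 library. That of the sensitized strains, 4, became 0 at an adjusted p under 0.01 (139 unadjusted), 8 under 0.1, 0 with such errors (71 unadjusted) and 0 by limma (407 unadjusted), 0 to 5 without 1 library. The overlap of the sensitized strains became 22 higher and 108 lower with limma calls and no shared library, but 0 and 1 with the spread pooled over 7 libraries. The 3MBPP1 overlap of 20 higher features became 10 at an adjusted p under 0.01 and 12 at 2-fold.

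With an estimated correlation 0 lists passed in each of the 4 tables and in the first 3 differences (camera on the recovered reads, 2, 3, 0, 0, 3, 2 and 1 lists at an unadjusted p under 0.05), and 1 in the difference of the sensitized strains. This setting changes the statistic along with the correlation, and for CMK in hrr25is it includes the shared library. Fisher tests of called members passed 8, 8, 1 and 1 lists in the tables and 1, 1, 3 and 1 in the differences. A preset correlation of 0.05 passed 4 lists for CMK in WT and 6 for the difference of 3MBPP1 effects; log2 values in place of the statistic passed 8 for that difference and 7 for that of CMK effects. Of named genes and markers, 76 alternative values kept their side of the threshold, 28 kept direction and lost it, and 15 were percentiles of a marker's count on another scale.

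No paired analysis was possible because the deposited tables hold condition means and the recovered libraries carry no replicate number, so the planned replicate block was not run. The count-model tests, quasi-likelihood and size factor, were planned for tables with count columns and were not run; limma was used on the recovered reads. In simulations limma called 41.1% of 2-fold changes for 3MBPP1 in hrr25as, with 4275991 to 6592340 reads per library, and 21.5% for CMK in WT. The dispersion put into these simulations, the same for all genes of a table, was 0.0411 and 0.068, against 0.0144 for 3MBPP1 in WT. Depth was 9568820 to 34122412 reads for CMK in WT and 10505164 to 13998631 for 3MBPP1 in WT. This argues against depth as the main reason for the low share in CMK in WT. For 3MBPP1 in hrr25as, how much is due to depth and how much to spread was not tested.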

Other observations

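The 3 own libraries of the hrr25is table, read with limma, were set beside the hrr25as table only after their values were seen.

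Several genes moved alike in hrr25as with 3MBPP1 and in the single own library of condition B of hrr25is with CMK, and were picked for that. With the spread pooled over the 7 distinct CMK libraries limma called only PHO5 in hrr25is, and none of the genes named here. ADE17, of purine synthesis, had log2 fold changes of -2.52 in the authors' table of hrr25as and -3.05 by limma in the own libraries of hrr25is, against 0.27 and 0.00 in the deposited tables of WT with 3MBPP1 and CMK. REC104 had 2.68 and 3.54, against -0.25 and 0.76. SNR71 had 2.65 and 2.05, against -1.83 and 1.51; it lies at 411228 to 411317 on chromosome VIII, near REC104 at 412907 to 413455. CTR2, a copper transporter, had 2.67 in the own libraries of hrr25is and a deposited 1.98 in hrr25as, which did not pass (adjusted p = 0.66).

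For HSP12 and some transporter genes the call in the authors' test differed between tables or did not follow the size of the fold change, and the cause was not tested. HSP12 had a deposited log2 fold change of 2.44 for 3MBPP1 in WT (adjusted p = 0.164) and 2.99 in hrr25as (adjusted p = 2.83e-05). YOR1 and PDR5, which rose in WT, had 1.24 and 1.53 in the deposited table of hrr25as (adjusted p = 0.74 and 0.49). HXT1, a low-affinity glucose transporter, had -0.97 in WT with 3MBPP1 (adjusted p = 1.72e-04) and -4.96 in hrr25as (adjusted p = 0.13), and in hrr25is a deposited 3.08 (adjusted p = 0.414) that turns to -2.28 by limma without the shared library.

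The share of reads from small nucleolar and spliceosomal RNA genes differed between sets of libraries: 31.4% to 38.2% for 3MBPP1 in WT, 5.14% to 6.39% for 3MBPP1 in hrr25as, 9.14% to 14.1% for CMK in WT and 14.1% to 18.1% for CMK in hrr25is.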
